A study of Mus musculus with 12 samples.

How the data were processed

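Adherent peritoneal macrophages of C57BL/6 mice aged 8 weeks were compared in 3 groups of 4 arrays each: vehicle control, IL4 at 10 ng/ml, and IL4 at 10 ng/ml with emodin, a plant anthraquinone, at 50 µM. Total RNA was labelled with a single dye, Cy3, and read on Agilent mouse expression arrays. The sample descriptions give a treatment of 6 h, while the treatment protocol speaks of an overnight stimulation, and this difference could not be settled from the labels. The labels do not say whether an array holds RNA of a single mouse or of pooled mice, and the series text calls the 4 arrays of a group biological replicates without saying what was separate, so p-values measure the spread between these samples, part of which may be technical. The sample labels name peritoneal macrophages, as used in this text, while the design text of the series speaks of peripheral white blood cells, and which holds was not settled here. Groups and replicate numbers 1 to 4 were taken from the sample titles. Control and IL4 arrays lay on one slide and all 4 emodin arrays on another, so slide and emodin cannot be told apart. All control and emodin arrays lay in row 2 of their slide and all IL4 arrays in row 1. Slide row and IL4 therefore cannot be told apart either. Within a slide, the replicate number was also the column of the array.

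Each array came with a scanner file and the series with a value table. The scanner files hold, per the file headers, spot intensity from Agilent Feature Extraction 10.7.3.1, which subtracted background within the array. The deposited value table holds log2 values that were quantile-normalized and then centred on the median of each probe over the 12 arrays. The table was recomputed from the scanner files with a correlation of 1.00 on every array, and it served as an alternative. The mean signal column needed for normexp background correction was absent, so the median spot signal took its place.

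The arrays carried 55681 probes. Gene symbols came from matching each probe's transcript identifier, without its version, to the mouse RefSeq gene table, which gave 27509 probes a single symbol and left 28172 unnamed. Control spots and spots marked as outliers by the scanner software were left out, and spots of the same probe were averaged. The main values were log2 intensity minus the 75th percentile of each array. All directions in the text are therefore relative to the 75th percentile of the array. Probes were kept where they lay well above background on all 4 arrays of at least 1 group, which left 27705. Each gene was represented by its probe with the highest mean, giving 20862 genes tested, of which 13197 had a symbol. A gene that lay below background on all arrays of the dimmer group is given as "at least" a fold value, which was computed from the background limit.

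Differences were fitted with limma 3.58.1 in R 4.3.3, as 3 group means over all 12 arrays (9 residual degrees of freedom), with moderated two-sided tests and Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p below 0.05. Fixed gene lists were tested with camera at its preset correlation of 0.01, adjusted over the 32 of 33 lists that had at least 3 tested genes. Camera sets a list against all other tested genes, so its calls with no filter on dim probes also depend on the undetected genes added. Beside each call stands the adjusted p with an estimated correlation, and the list's gene counts are also given adjusted over the list alone. The design, the 33 lists, the markers and the named-gene rule were written before the data were examined. That rule took the 10 largest called rises and falls per comparison among symbols whose groups did not overlap, up to 4 called members of each list (the text gives a subset), and 21 fixed genes; some genes it took are not reported here. Single measures of the arrays were compared with exact permutation tests (two-sided, 4 arrays against 4), whose smallest possible p is 0.0286. Precision is limited by the 4 arrays per group.

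Tables were handled with data.table (version 1.17.8) and figures drawn with Python 3.11.15 and matplotlib 3.10.9. The fit was tested on simulated data made from the means and spreads of the 20862 genes, with 200 genes changed. For IL4 against control, it recovered 44.8% of the genes changed 1.5-fold, 86.6% of those changed 2-fold and 95.5% of those changed 4-fold, with 9 false calls. For IL4 plus emodin against IL4 it recovered 53.7%, 80.6% and 100% of the same sizes, with 5 false calls. For IL4 plus emodin against control it recovered 52.2%, 80.6% and 100%, with 8 false calls. The simulated noise was independent, without pairing of arrays or a slide difference. Far more genes were called in the data than were changed here, which loosens the cutoff, so these shares do not carry over to the real comparisons.

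The labels give every group the numbers 1 to 4 without saying that they mark the same animals. For IL4 against control, arrays with the same number deviated together from their group means, with correlations across genes of 0.311 to 0.524 over the 4 pairs. The numbers therefore pair these arrays, and for this comparison a fit with the number as a block is printed beside a result where it changes a call. Other alternatives were quantile, median and spike-in scaling, normexp background correction, the deposited value table, no filter or a stricter filter on dim probes, other ways of joining probes, another variance model, the compared groups alone, labelled sex as a covariate, a plain per-gene test, a 2-fold threshold, and each array left out in turn. Spike-in, external-control and negative-control spots took no part in these tests.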

Results

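Expression of 20862 genes was measured on 12 arrays of mouse peritoneal macrophages, 4 each for vehicle control, IL4, and IL4 with emodin. The series title names the question: whether emodin, a plant anthraquinone, acts on the alternative activation that IL4 induces in these cells. Signal lay well above background for 50.2% ± 0.550 (SD, n = 4) of probes on control arrays, 52.3% ± 0.994 (SD, n = 4) on IL4 arrays and 48.3% ± 0.963 (SD, n = 4) on emodin arrays. The 75th percentile of intensity was 730 ± 74.0, 776 ± 24.5 and 488 ± 31.4 (SD, n = 4 each), and the emodin arrays lay below the IL4 arrays (exact permutation test, two-sided, p = 0.0286). Arrays of the same group correlated at 0.991 to 0.997 across genes, and arrays of different groups at 0.955 to 0.988.

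IL4 against control asks what the cytokine alone does to these macrophages. IL4 raised *Cish*, which encodes a feedback inhibitor of JAK-STAT signalling, by a log2 difference of 8.90 ± 0.14 (SE, n = 4 per group; limma adjusted p = 4.05e-12). *Arg1* rose by 6.91 ± 0.19, *Pdcd1lg2* by 5.99 ± 0.11, *Socs1* by 4.88 ± 0.13 and *Irf4* by 4.78 ± 0.16. Of the 20862 genes, 3659 were called, 1873 higher and 1786 lower, and 567 and 257 of these changed at least 2-fold. The genes with the largest rises also included *Mrgprg* (6.54), *Tmem26* (6.45), *Tuba8* (5.64), *Ch25h* (5.23) and *Rbp4* (5.21). *Adipoq* rose at least 81.7-fold and *Il31ra* at least 24.2-fold, both from below background. The largest falls were in *Slc40a1* (-2.53 ± 0.26), which encodes the iron exporter ferroportin, *Pram1* (-2.35), *Sema4d* (-2.29), *Cxcl10* (-2.25) and *Zranb3* (-2.19). *Fcrl1* fell at least 4.13-fold, *Fpr2* at least 3.68-fold, *Zan* at least 3.12-fold, *Skint3* at least 2.59-fold and *Rufy4* at least 2.15-fold, each to below background.

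The alternative activation list rose with IL4, with a median log2 difference of 2.37 over 32 genes (adjusted p = 2.14e-23, and 0.0482 with an estimated correlation). 26 of its genes were called higher and 1 lower over all genes, or 28 and 2 adjusted over the list alone. *Ocstamp* rose by 3.61 ± 0.16, *Ccl24* by 3.09 ± 0.34, *Chil3* by 2.66 ± 0.72 (adjusted p = 0.0234, but 0.0730 with the plain per-gene test), *Fn1* by 2.44 ± 0.19 and *Mrc1*, the mannose receptor, by 2.02 ± 0.22. *Ccl17* rose at least 4.20-fold from below background, and *Ccl22* was too dim to test. *Retnla* differed by 2.35 ± 1.04 and was not called (adjusted p = 0.155), but it was called with the replicate number as a block (adjusted p = 0.00388). Its control arrays ranged from 1.13 to 5.74 on the log2 scale.

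Of the IL4 receptor and JAK-STAT list, 7 of 22 genes were called higher and 2 lower (9 and 2 adjusted over the list alone), with a median of 0.13 (adjusted p = 0.00147, but 0.415 with an estimated correlation). *Socs2* rose by 3.99 ± 0.28, *Jak2* by 1.63 ± 0.09 and *Il4ra* by 0.83 ± 0.15, while *Stat6* itself did not change (-0.14 ± 0.08, adjusted p = 0.254). The integrated stress response list rose, with 19 of 26 genes higher (20 adjusted over the list alone) and a median of 0.54 (adjusted p = 2.06e-11, but 0.288 with an estimated correlation). *Slc7a5* rose by 1.15 ± 0.14, *Atf3* by 1.01 ± 0.07, *Phgdh* by 0.99 ± 0.12 and *Atf5* by 0.85 ± 0.10. The ER chaperone list was called with 3 of 18 genes higher (3 adjusted over the list alone), led by *Pdia4* at 3.01 ± 0.14. Its adjusted p was 0.0350, but 0.561 with an estimated correlation and 0.0989 with normexp then quantile.

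Genes of the NRF2 oxidative stress list fell with IL4: 9 of 29 were lower and 1 higher (13 and 1 adjusted over the list alone), with a median of -0.27 (adjusted p = 0.000364, but 0.395 with an estimated correlation). *Gsr* fell by 0.82 ± 0.09 and *G6pdx* by 0.52 ± 0.07, while *Hmox1* stayed just outside the threshold (-0.36 ± 0.11, adjusted p = 0.0505; 0.0171 with the number as a block) and *Nqo1* did not change (-0.16 ± 0.13, adjusted p = 0.438). Of 24 cholesterol synthesis genes, 4 fell and none rose (5 lower and 1 higher adjusted over the list alone; median -0.28, adjusted p = 0.00748, but 0.732 with an estimated correlation and 0.0788 with no filter on dim probes). *Stard4* fell by 0.51 ± 0.11 and *Fdft1* by 0.48 ± 0.14 (0.12 with its other probe), and neither was called with spike-in scaling (adjusted p = 0.0975 and 0.171). Smaller list rises were called for large peritoneal macrophage identity (8 of 24 genes, 9 adjusted over the list alone; adjusted p = 0.0117, but 0.395 with an estimated correlation), with *F10* at 1.27 ± 0.10 (its other probe gave -0.27) and *Bhlhe40* at 0.96 ± 0.10. H3K27 methylation genes were called with 4 of 17 higher (4 adjusted over the list alone). Their adjusted p was 0.0169, but 0.395 with an estimated correlation, and the call was lost with normexp then quantile (adjusted p = 0.05). *Kdm6b* rose by 1.16 ± 0.19, *Jarid2* by 0.65 ± 0.12 and *Phf19* by 0.53 ± 0.07, whereas *Ezh2* did not change (-0.16 ± 0.08, adjusted p = 0.232). Lysosome genes were called with 5 of 27 higher (6 adjusted over the list alone; adjusted p = 0.0201, but 0.395 with an estimated correlation), including *Psap* at 0.75 ± 0.10.

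Inflammatory genes moved both ways with IL4, and the classical inflammatory list of 29 genes was not called (6 higher, 9 lower; adjusted p = 0.692). *Ccl7* rose by 4.34 ± 0.46 and *Cd40* by 1.49 ± 0.13, *Il6* rose at least 4.05-fold and *Ptgs2* at least 3.98-fold, while *Tnf* fell by 1.09 ± 0.16. *Nos2* (0.09 ± 0.23, adjusted p = 0.839) and *Il1b* (0.11 ± 0.17, adjusted p = 0.732) did not change. Of the interferon-stimulated list, 6 genes were higher and 5 lower (adjusted p = 0.957), with *Irf1* up by 1.05 ± 0.11 and *Ifit3* down by 1.24 ± 0.15. In the immediate early list (7 higher, 3 lower; adjusted p = 0.158) *Ier3* rose by 3.68 ± 0.15 and *Egr2* by 1.44 ± 0.13. In the matrix remodelling list (4 higher, 6 lower; adjusted p = 0.627) *Mmp13* rose by 3.05 ± 0.30. *Cyp1b1*, of the AHR target list (2 of 8 genes higher; adjusted p = 0.206), differed by 0.51 ± 0.40 (adjusted p = 0.443; 0.0395 with the number as a block). MHC class II genes showed no call for the list (1 of 10 higher, median 0.31, adjusted p = 0.158, and 0.835 with an estimated correlation), but did with the number as a block (adjusted p = 0.0161). The heat shock, p53 target, LXR target, fatty acid, glycolysis and hypoxia, cell cycle, complement and efferocytosis, ribosomal protein and oxidative phosphorylation lists were not called (adjusted p = 0.0768 to 0.957). With no filter on dim probes the heat shock (adjusted p = 0.00421), MHC class II (adjusted p = 0.00431) and immediate early (adjusted p = 0.0468) lists were called. There the median of all genes, against which camera sets a list, moved from -0.03 to -0.13.

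Emodin with IL4 against IL4 alone asks which part of the IL4 state changes when the compound is present. *Irf4*, a transcription factor of the IL4 response, fell by 6.45 ± 0.16 with emodin (SE, n = 4 per group; limma adjusted p = 2.18e-10). *Socs1* fell by 4.49 ± 0.13, *Pdcd1lg2* by 3.30 ± 0.11, *Cish* by 2.77 ± 0.14 and *Arg1* by 2.70 ± 0.19, so that *Arg1* on emodin arrays was 6.49-fold lower than with IL4 alone. In all, 13750 genes were called, 8212 higher and 5538 lower, and 1768 and 2060 of them changed at least 2-fold. The falls with the largest log2 differences further included *Lipn* (-5.15), *Ch25h* (-5.09) and *Flt1* (-4.61). *Npas4* fell at least 24.3-fold, *Il31ra* at least 15.6-fold, *Ppargc1b* at least 11.6-fold, *Gapt* at least 6.07-fold and *Stxbp6* at least 5.28-fold, all to below background. Among the largest rises were *Cxcl2*, a neutrophil-attracting chemokine, at 6.03 ± 0.22 and *Ankrd33b* at 5.90 ± 0.12. From below background, *Fam71a* rose at least 109-fold, *Tmem184a* at least 40.5-fold, *H2bc23* at least 19.9-fold, *Rufy4* at least 15.5-fold, *H1f3* at least 15.3-fold, *Hsh2d* at least 14.8-fold, *Dppa4* at least 11.9-fold and *Tssk3* at least 7.66-fold. Every value in this comparison carries the slide and slide row differences as well as the compound, and no array allows these to be separated. With the spike-in controls as the scale, the median difference of all genes moved from 0.17 to -0.92, so rises smaller than about 1.09 turned into falls.

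The alternative activation list fell with emodin by a median of 1.57 over 32 genes (adjusted p = 1.73e-05, but 0.484 with an estimated correlation), with 23 genes lower and 6 higher (24 and 6 adjusted over the list alone). *Batf3* fell by 3.91 ± 0.18, *Ocstamp* by 3.66 ± 0.16, *Retnla* by 3.55 ± 1.04 (adjusted p = 0.0102, but 0.0561 with number 1 of each group left out), *Ccl24* by 2.68 ± 0.34 and *Mrc1* by 0.94 ± 0.22, and *Ccl17* fell at least 2.66-fold. *Chil3* differed by -1.52 ± 0.72 and was not called (adjusted p = 0.0803), but it was with the compared groups alone (adjusted p = 0.0339). In the IL4 receptor and JAK-STAT list, 11 of 22 genes fell and 5 rose (11 and 5 adjusted over the list alone; median -0.18, adjusted p = 0.0383, but 0.798 with an estimated correlation, 0.105 with quantile and 0.254 with spike-in scaling). *Jak2* fell by 2.00 ± 0.09, *Ptpn6* by 1.58 ± 0.07, *Il4ra* by 1.40 ± 0.15 (0.17 with its other probe) and *Stat6* by 1.00 ± 0.08.

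Cholesterol synthesis genes fell as a group: 20 of 24 were lower and none higher (20 adjusted over the list alone), with a median of -1.20 (adjusted p = 2.74e-08, but 0.575 with an estimated correlation). *Idi1* fell by 2.54 ± 0.15, *Stard4* by 2.29 ± 0.11 (its other probe gave -1.24) and *Hmgcs1* by 1.71 ± 0.11. Of 29 interferon-stimulated genes, 17 fell and 3 rose (18 and 3 adjusted over the list alone; median -0.38, adjusted p = 0.000680, but 0.461 with an estimated correlation), among them *Cmpk2* (-2.96 ± 0.13), *Igtp* (-1.66 ± 0.07), *Gbp2* (-1.48 ± 0.10) and *Stat2* (-1.47 ± 0.09). Of 18 immediate early genes, 10 fell and 3 rose (10 and 3 adjusted over the list alone; median -0.33, adjusted p = 0.0354, but 0.484 with an estimated correlation, 0.0882 with quantile and 0.293 with spike-in scaling). *Egr2* fell by 2.31 ± 0.13, *Ier3* by 2.04 ± 0.15 and *Junb* by 0.89 ± 0.09, while *Dusp1* rose by 1.27 ± 0.11 (0.18 and not called with spike-in scaling).

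Targets of p53 rose with emodin: 13 of 15 were higher and none lower (13 adjusted over the list alone), with a median of 1.05, but -0.04 with spike-in scaling (adjusted p = 0.000365, but 0.461 with an estimated correlation). *Phlda3* rose by 3.58 ± 0.21, *Pmaip1* by 1.77 ± 0.10, *Mdm2* by 1.66 ± 0.08 and *Bbc3* by 1.66 ± 0.10. All 38 cytosolic ribosomal protein genes were higher (38 adjusted over the list alone; median 0.75, adjusted p = 2.74e-08, but 0.629 with an estimated correlation), such as *Rps9* (0.88), *Rplp2* (0.80) and *Rplp0* (0.76), but their median was -0.33 with spike-in scaling and 0.07 with quantile scaling, where the list was not called (adjusted p = 0.333). Of 27 lysosome genes, 22 were higher and 2 lower (22 and 2 adjusted over the list alone; median 0.55, adjusted p = 0.0198, but 0.484 with an estimated correlation), with *Ctsa* at 0.78 ± 0.08 and *Gpnmb* at 0.75 ± 0.06, though neither was called with quantile scaling (adjusted p = 0.585 and 0.826). That median was -0.54 with spike-in scaling and -0.01 with quantile scaling, and *Tfe3* fell by 1.22 ± 0.09 under the main scaling. The lysosome list was not called with spike-in scaling, quantile scaling or no filter on dim probes (adjusted p = 0.917, 0.921 and 0.131). Relative to the other genes, camera with spike-in scaling called the p53 and ribosomal protein lists up (adjusted p = 1.6e-07 and 0.00719), though their medians did not rise there.

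Several lists changed at many genes without being called, while 65.9% of all tested genes were called in this comparison. Of 29 classical inflammatory genes, 15 were higher and 9 lower (adjusted p = 0.603, but 0.000593 with spike-in scaling, where the median was -0.59 and the test pointed up): *Cxcl1* rose by 4.56 ± 0.41, *Tnf* by 1.41 ± 0.16 (0.33 and not called with spike-in scaling) and *Nfkbia* by 1.06 ± 0.09. *Il1b* fell at least 1.08-fold to below background, while *Nos2* was not called (0.50 ± 0.23, adjusted p = 0.0785). *Il6* was called lower (adjusted p = 0.00644) with only 1 of 4 emodin arrays above background, and not with normexp and the 75th percentile (adjusted p = 0.268). Of 17 H3K27 methylation genes, 11 were higher and 4 lower (adjusted p = 0.603), with *Rnf2* up by 1.07 ± 0.09, *Ezh2* up by 1.02 ± 0.08, *Kdm6b* down by 0.87 ± 0.19 and *Cbx8* down at least 10.6-fold. In the heat shock list (4 higher, 6 lower of 13; adjusted p = 0.603) *Hspa1a* rose by 2.23 ± 0.16, and in the ER chaperone list (6 higher, 9 lower of 18; adjusted p = 0.278, but 0.0320 with spike-in scaling) *Xbp1* fell by 1.41 ± 0.08. In the integrated stress response list (10 higher, 8 lower of 26; adjusted p = 0.897) *Ddit4* rose by 2.05 ± 0.17 and *Ppp1r15a* by 1.43 ± 0.09. In the NRF2 list (12 higher, 5 lower of 29; adjusted p = 0.629) *Hmox1* rose by 0.33 ± 0.11 (0.07 and not called with quantile scaling, adjusted p = 0.561, and -0.76 with spike-in scaling), and *Nqo1* was not called (0.06 ± 0.13, adjusted p = 0.683; -1.02, adjusted p = 6.98e-06, with spike-in scaling). *Cyp1b1* of the AHR list (2 higher, 3 lower of 8; adjusted p = 0.603) was not called (-0.49 ± 0.40, adjusted p = 0.293; -1.58, adjusted p = 0.00251, with spike-in scaling). The MHC class II, LXR target, fatty acid, glycolysis and hypoxia, cell cycle, complement, large peritoneal macrophage and oxidative phosphorylation lists were not called (adjusted p = 0.303 to 0.824). Nor was the matrix remodelling list (adjusted p = 0.303, but 0.00376 with spike-in scaling). With no filter on dim probes the MHC class II (adjusted p = 0.0300) and cell cycle (adjusted p = 0.0121) lists were called lower. The ER chaperone list was called there too (median -0.14, adjusted p = 0.0071). Its median was -0.14 with the filter as well, while the median of all genes moved from 0.17 to 0.49 without it. These calls therefore also reflect the genes that the lists were set against.

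**Figure D1:**
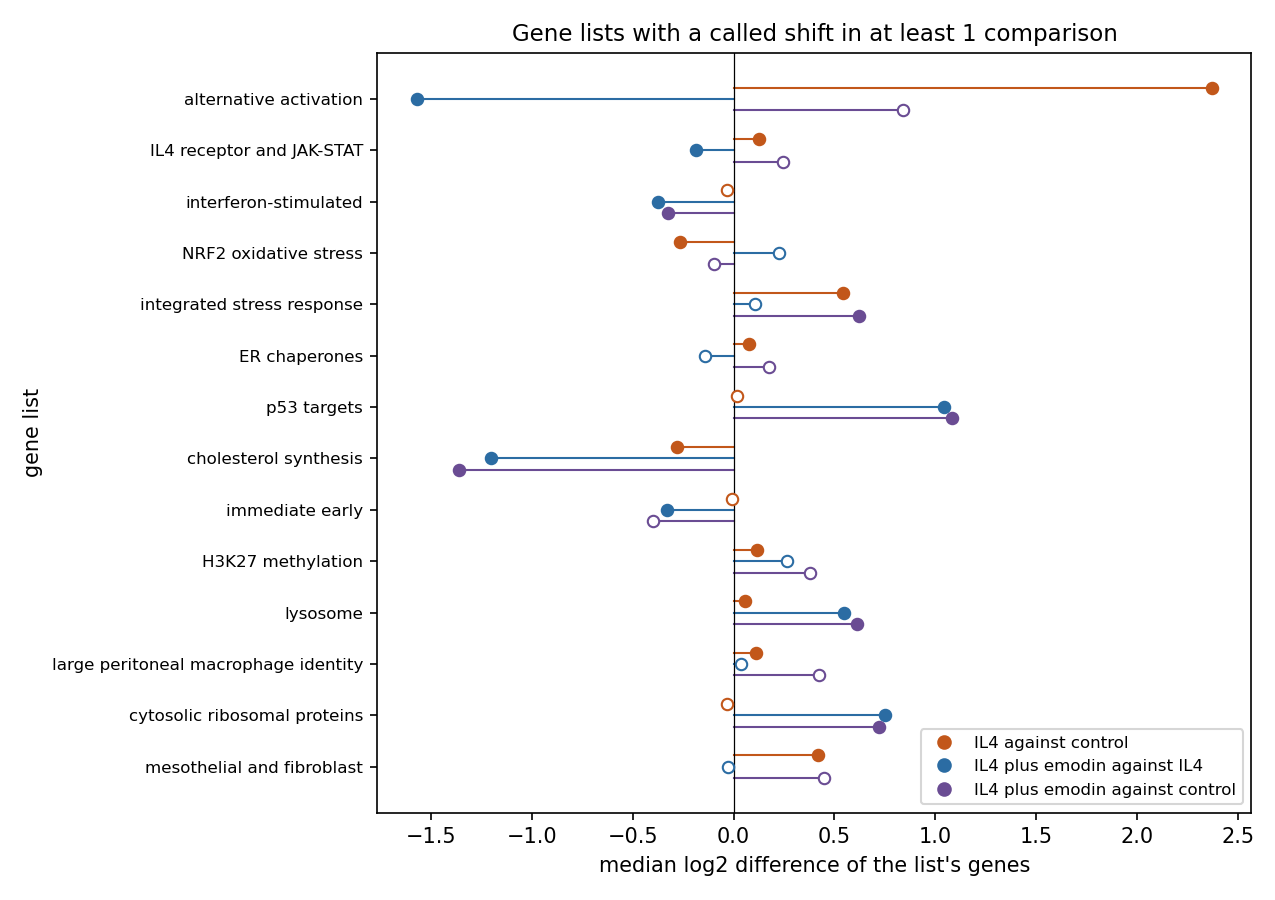
Median log2 difference of the genes in each list (horizontal axis) for the 3 comparisons, for every list called in at least 1 of them; filled points are called by camera at an adjusted p below 0.05 and open points are not. The alternative activation list lay at 2.37 for IL4 against control and at -1.57 for IL4 plus emodin against IL4.

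Emodin with IL4 against control asks how far the treated cells stayed from the resting state. *Arg1* remained above its control level by 4.21 ± 0.19 (SE, n = 4 per group; limma adjusted p = 8.36e-09), *Cish* by 6.13 ± 0.14 and *Pdcd1lg2* by 2.69 ± 0.11. *Irf4* fell below control by 1.67 ± 0.16 and *Stat6* by 1.14 ± 0.08. In this comparison 13125 genes were called, 7780 higher and 5345 lower, and 1631 and 1843 of them changed at least 2-fold. The balance rests on the scaling, as quantile scaling gave 5587 higher and 6300 lower, and spike-in scaling 860 and 15769. The largest rises included *Ankrd33b* (5.50) and *Rab15* (5.48, but 1.38 with its other probe), and from below background *Fam71a* (at least 101-fold), *Tmem184a* (at least 37.8-fold), *H2bc23* (at least 18.6-fold), *Ccl12* (at least 17.5-fold), *H1f3* (at least 14.2-fold), *Hsh2d* (at least 13.8-fold) and *Slc25a2* (at least 12.5-fold). The largest falls included *Bbs12* (-4.03), *Nab2* (-3.84), *Adora3* (-3.73), *Arhgef10l* (-3.63) and *Galnt9* (-3.58). *Npas4* fell at least 20.1-fold, *Fasn*, which encodes fatty acid synthase, at least 5.52-fold, *Gpr85* at least 4.98-fold, *Gapt* at least 4.73-fold and *Usp2* at least 2.70-fold, all to below background.

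Of the fixed genes, *Mrc1* lay above control by 1.08 ± 0.22, *Ezh2* by 0.86 ± 0.08, *Nos2* by 0.59 ± 0.23 (adjusted p = 0.0437) and *Socs1* by 0.39 ± 0.13, but with spike-in scaling *Mrc1* was not called (0.12, adjusted p = 0.590) and the other 3 turned negative. *Nos2* also lost its call with quantile scaling (adjusted p = 0.0831), no filter on dim probes (adjusted p = 0.0612) and the plain per-gene test (adjusted p = 0.0532). *Socs1* lost its call with the plain per-gene test (adjusted p = 0.0639) and with number 1 of each group left out (adjusted p = 0.0938). *Il4ra* lay 0.57 ± 0.15 below control, while its other probe gave 0.29 and the mean of the probes was not called (adjusted p = 0.341). *Chil3* (1.14 ± 0.72, adjusted p = 0.184), *Ccl24* (0.41 ± 0.34, adjusted p = 0.314), *Tnf* (0.32 ± 0.16, adjusted p = 0.0949), *Kdm6b* (0.29 ± 0.19, adjusted p = 0.209) and *Retnla* (-1.19 ± 1.04, adjusted p = 0.336, but 0.0471 with spike-in scaling) were not called against control, nor were *Hmox1* (-0.03), *Nqo1* (-0.10) and *Cyp1b1* (0.01). *Hmox1* was called lower with quantile scaling (-0.30, adjusted p = 0.0165), and *Hmox1* (-0.99) and *Nqo1* (-1.06) with spike-in scaling. *Il6* and *Ccl17* lay below background on most or all arrays of both groups, and *Il1b* fell to below background, though not with normexp and the 75th percentile (adjusted p = 0.996).

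Cholesterol synthesis genes, with *Idi1* at -2.92 ± 0.15, *Stard4* at -2.81 ± 0.11 (its other probe gave -1.77) and *Lss* at -1.87 ± 0.12, lay below control. Of 24, 21 were lower and none higher (21 adjusted over the list alone), with a median of -1.36 against control (adjusted p = 5.97e-10, but 0.621 with an estimated correlation). Interferon-stimulated genes lay below it too (17 of 29 lower and 4 higher, 19 and 4 adjusted over the list alone; adjusted p = 0.000459, but 0.277 with an estimated correlation), including *Cmpk2* (-3.16 ± 0.13) and *Igtp* (-1.76 ± 0.07). Targets of p53 lay above control (13 of 15 higher and 1 lower, the same adjusted over the list alone; median 1.08, but 0.13 with spike-in scaling; adjusted p = 0.000316, but 0.277 with an estimated correlation), with *Phlda3* at 3.17 ± 0.21, *Cdkn1a* at 2.39 ± 0.11 and *Mdm2* at 1.78 ± 0.08. The integrated stress response list was higher (17 of 26 higher and 3 lower, the same adjusted over the list alone; median 0.62, but -0.34 with spike-in scaling; adjusted p = 0.0171, but 0.898 with an estimated correlation), with *Ddit4* at 2.36 ± 0.17, *Ppp1r15a* at 1.96 ± 0.09 and *Atf3* at 0.98 ± 0.07 (0.02 with spike-in scaling). Lysosome genes (23 of 27 higher and 1 lower, 23 and 2 adjusted over the list alone; adjusted p = 0.000419, but 0.277 with an estimated correlation) included *Lamp1* at 0.88 and *Gpnmb* at 0.76. All 38 ribosomal protein genes were again higher (38 adjusted over the list alone; adjusted p = 1.36e-08, but 0.730 with an estimated correlation), *Rps10* by 0.85 and *Rplp0* by 0.79, and the medians of both lists were negative with spike-in scaling, at -0.35 for lysosome genes and -0.24 for ribosomal protein genes. With quantile scaling neither list was called (medians 0.10 and 0.06, adjusted p = 0.326 for both). Relative to the other genes, camera with spike-in scaling called the p53, integrated stress response and ribosomal protein lists up (adjusted p = 1.33e-08, 0.00657 and 0.00167). The lysosome list was not called there (adjusted p = 0.26).

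The alternative activation list was no longer called against control (15 higher, 6 lower of 32; median 0.84, adjusted p = 0.258). It was called with spike-in scaling (median -0.12, though the test pointed up; adjusted p = 7.5e-06) and with fry (adjusted p = 0.000683). *Pparg* was still up by 1.73 ± 0.09 and *Dcstamp* down by 2.77 ± 0.16. Of 22 IL4 receptor and JAK-STAT genes, 9 were higher and 8 lower (adjusted p = 0.982; the median was 0.25 while the test pointed down), *Socs3* by 2.60 ± 0.11 and *Ptpn6* by -2.22 ± 0.07. Of 29 classical inflammatory genes, 13 were higher and 5 lower (adjusted p = 0.559, but 0.00105 with spike-in scaling), with *Cxcl2* up by 4.81 ± 0.22 and *Ptgs2* up at least 11.1-fold. In the matrix remodelling list (15 higher, 3 lower of 26; adjusted p = 0.235, but 0.00657 with spike-in scaling) *Mmp13* rose by 5.06 ± 0.30. The other 14 pathway lists were not called (adjusted p = 0.131 to 0.982). With quantile scaling the NRF2 list was called lower (median -0.35, adjusted p = 0.00976) and the H3K27 methylation list higher (0.37, adjusted p = 0.0384). With no filter on dim probes the cell cycle (adjusted p = 0.00503) and NRF2 (median -0.10, adjusted p = 0.0172) lists were called lower. The NRF2 median was -0.10 with the filter too, while the median of all genes moved from 0.15 to 0.38 without it.

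A further question is how much of the IL4 response emodin took back. Of the 3659 genes that IL4 changed, 2090 moved the opposite way with emodin and 702 moved further the same way. Of the 1873 genes that IL4 raised, 56.5% fell with emodin, and of the 1786 it lowered, 57.8% rose. Lists drawn independently would share 1200 opposite and 1211 same-way genes. Both contrasts use the IL4 arrays, so the covariance of their log2 differences, -0.161, was set beside that of unchanged groups in simulation, -0.0161. With the IL4 arrays split between the contrasts, 1171 to 1359 genes moved back and 341 to 443 moved further, and the covariance stayed between -0.149 and -0.142. All IL4 arrays shared a slide row that held no control or emodin array. An effect of that row would enter both contrasts with opposite sign, and neither the split nor the simulation can exclude it. The 567 genes that IL4 raised at least 2-fold had a median log2 difference of 1.57 with IL4, -1.20 from IL4 to emodin, and 0.66 for emodin against control, and 402 of them fell and 53 rose further. With spike-in scaling the last median was -0.30. The 257 genes that IL4 lowered at least 2-fold had a median of -1.26 with IL4, 0.95 from IL4 to emodin and -0.38 for emodin against control, and 169 of them rose and 37 fell further. Their move back rests on the scaling, as the median from IL4 to emodin was 0.72 with quantile and -0.13 with spike-in scaling. Both sets were chosen with the same IL4 arrays that measure the move back. With those arrays split, the medians from IL4 to emodin were smaller in size. They lay at -1.18 to -1.08 for genes raised at least 2-fold and 0.72 to 0.90 for genes lowered at least 2-fold.

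Among the 26 alternative activation genes that IL4 raised, emodin left 5 below their control level: *Irf4*, *Batf3*, *Klf4*, *Egr2* and *Matk*. Another 7 were lowered and no longer called against control: *Ch25h*, *Flt1*, *Ocstamp*, *Cdh1*, *Ccl24*, *Alox15* and *Myc*, although *Cdh1* (0.95) and *Alox15* (0.93) still lay above it. For 9, including *Arg1*, *Pdcd1lg2*, *Slc7a2*, *Mrc1* and *Tfrc*, the level was lowered but stayed above control, although 1 of the 9, *Ccl17*, lay below background in both of those groups. With spike-in scaling only 3 of the 9, *Arg1*, *Pdcd1lg2* and *Slc7a2*, were called above control, and 3 of the 7, *Flt1*, *Ocstamp* and *Myc*, were called below it. *Pparg* (0.39 ± 0.09) and *Atp6v0d2* (0.47) rose further with emodin, but not with quantile scaling (-0.06 and -0.13). With spike-in scaling both were called lower (-0.69 and -0.61, adjusted p = 0.000136 and 0.000312). Of the rest, *Chil4* (-1.87, adjusted p = 0.0511), *Chil3* and *Igf1* (0.18, adjusted p = 0.266) were not called, although *Chil3* was called lower with quantile scaling (-2.08, adjusted p = 0.0207). With spike-in scaling *Chil4* (-2.95), *Chil3* (-2.60) and *Igf1* (-0.90) were all called lower.

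**Figure D2:**
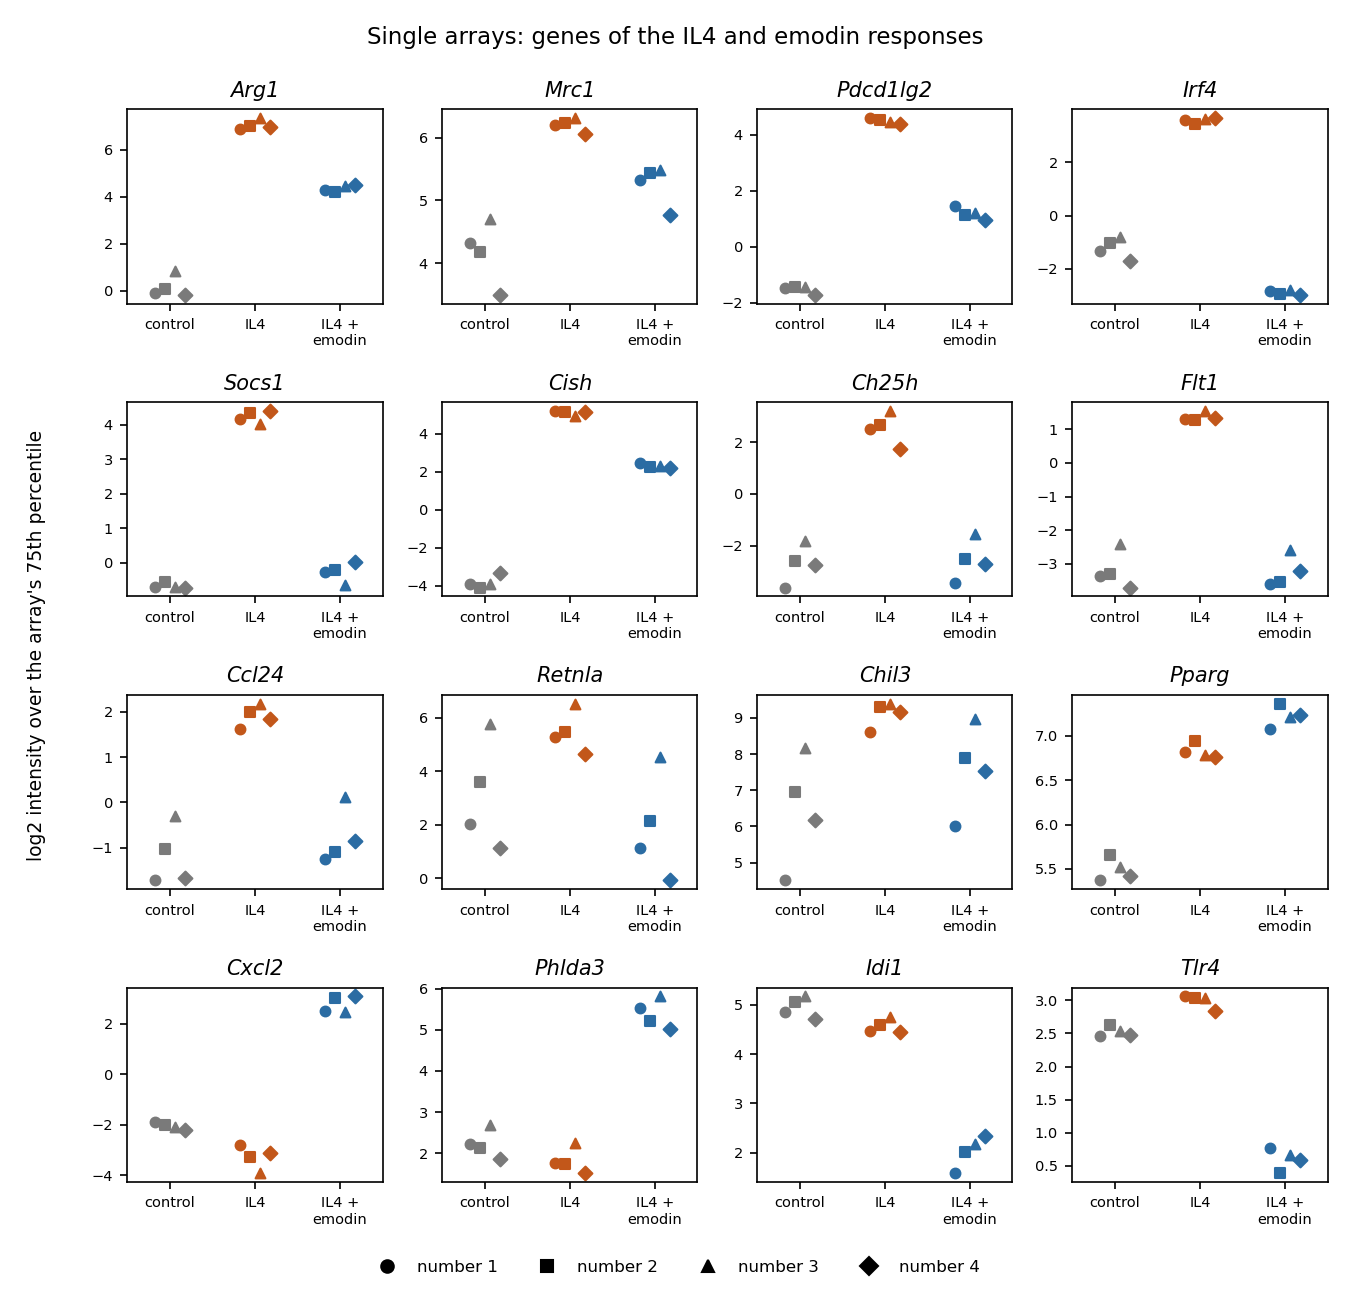
Log2 intensity over the 75th percentile of the array (vertical axis) for 16 genes on each of the 12 arrays, by group, with the replicate number as the marker. *Arg1* averaged 0.15 on control arrays, 7.06 on IL4 arrays and 4.37 on emodin arrays.

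Markers of other peritoneal cells were read on the same arrays. The mesothelial and fibroblast list rose with IL4 (4 of 17 genes, 4 adjusted over the list alone; median 0.42, adjusted p = 0.0337, but 0.874 with an estimated correlation and 0.118 with spike-in scaling), with *Lrrn4* up by 2.42 ± 0.67 (adjusted p = 0.0566 with the plain per-gene test), *Krt18* by 2.07 ± 0.32 and *Igfbp5* at least 5.50-fold. With emodin *Lrrn4* fell by 4.43 ± 0.67 and *Krt18* by 1.07 ± 0.32 (adjusted p = 0.0560 with the plain per-gene test), although that list was not called (2 of 17 lower; adjusted p = 0.461), nor was it against control (adjusted p = 0.832). It was called with no filter on dim probes against IL4 (adjusted p = 0.0349) and with spike-in scaling against control (adjusted p = 0.00280). Macrophage markers were not called as a list with IL4 (adjusted p = 0.294) or with emodin (adjusted p = 0.461; the median was 0.12, but the mean was -0.67 and the test pointed down), but single genes changed: IL4 raised *Csf1r* by 0.64 ± 0.12 and lowered *Cd14* by 0.84 ± 0.12. Emodin then lowered *Fcgr1* by 2.89 ± 0.17 and *Tlr4*, the endotoxin receptor, by 2.39 ± 0.09, and both *Fcgr1* (-3.46 ± 0.17) and *Tlr4* (-1.92 ± 0.09) lay below control. *Cd79b*, a B cell marker, fell by 2.16 ± 0.25 with emodin and the mast cell marker *Kit* rose by 1.92 ± 0.14. The B cell, T cell, mast cell, neutrophil, eosinophil and dendritic cell lists were called in no comparison (adjusted p = 0.158 to 0.957). With spike-in scaling, however, the T cell list was called for IL4 against control (adjusted p = 0.0351) and the mast cell list for emodin against control (adjusted p = 0.0331), and with no filter on dim probes the B cell list was called against control (adjusted p = 0.0469). The macrophage list was called for IL4 against control with no filter on dim probes (adjusted p = 0.0429). The natural killer list had fewer than 3 tested genes.

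**Figure D3:**
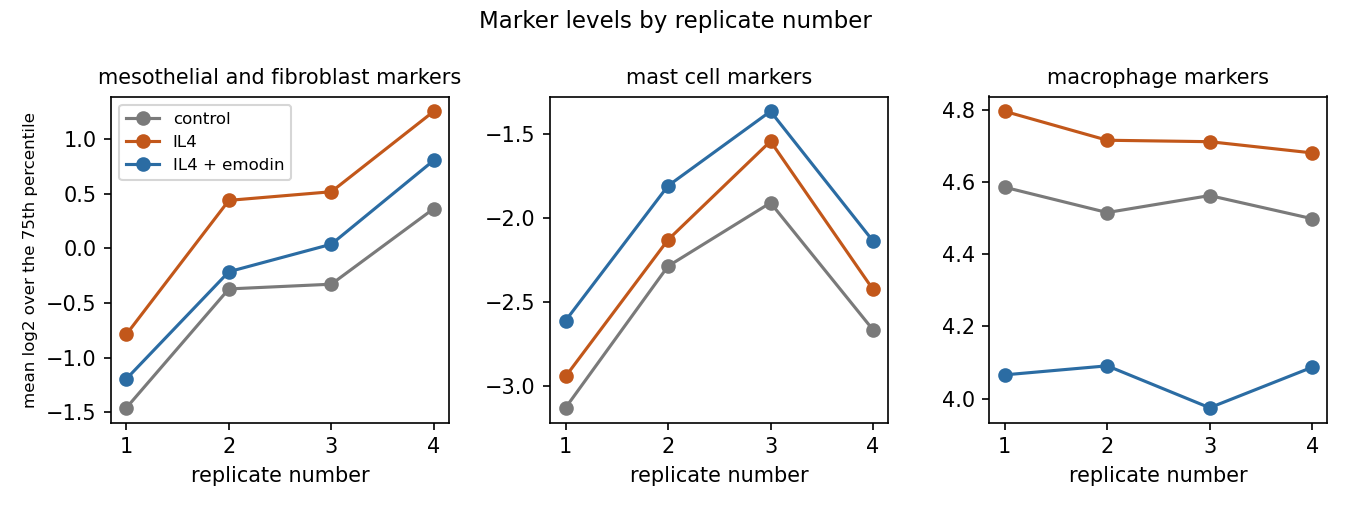
Mean log2 intensity over the 75th percentile of the array (vertical axis) of the mesothelial and fibroblast, mast cell and macrophage markers, against the replicate number, with 1 line per group. Fibroblast markers rose from number 1 to number 4 in every group, by 1.96 on average, and mast cell markers peaked at number 3.

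The labels name numbers 1 and 2 as female and 3 and 4 as male in every group. No gene differed by labelled sex in its response to IL4 or to emodin (0 called of 20862 in each test), and 272 and 507 genes lay below an unadjusted p of 0.05. Across genes, which are not independent replicates, the responses of arrays labelled female and male correlated at 0.878 for IL4 and 0.932 for emodin. *Xist*, expressed from the inactive X chromosome of females, lay well above background on all 12 arrays (0.61 ± 0.57 on arrays labelled female and 0.47 ± 0.48 on arrays labelled male; SD across the treatment groups, n = 6 each). The Y-linked genes *Ddx3y*, *Uty*, *Kdm5d* and *Eif2s3y* lay below it on all 12, so the arrays labelled male did not match their label and these comparisons give no measure of a sex difference.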

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

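Which of the 461 sets of 4 arrays held a value far from the other 3 was decided by a gap test fixed before the data were examined, and 29 sets passed its limit (23.1 by chance). Among the genes named above, an array stood low for *Bbc3* in the control group (gap ratio 0.908; 3.50 on control array 3 against 3.87 to 3.90 on the others). The same held for *Cd40* in the control (0.839) and IL4 (0.928) groups, and for *Hspa1a* (0.852), *Mdm2* (0.863), *Pdcd1lg2* (0.880) and *Tnf* (0.854) in the control group. In the IL4 group an array was low for *Mmp13* (0.889), *Ptgs2* (0.831) and *Tlr4* (0.861). In the emodin group an array was low for *Bhlhe40* (0.840), *Cd79b* (0.947), *Nqo1* (0.838) and *Stat6* (0.845). A high array was found for *Rab15* (0.882), *Socs1* (0.887) and *Tfe3* (0.921) in the control group, for *Flt1* (0.844) and *Stxbp6* (0.903) in the IL4 group, and for *Fam71a* (0.889), *Pram1* (0.930) and *Stat2* (0.849) in the emodin group. No array was removed.

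Of the gene lists, the median of the integrated stress response genes was low on control array 4 (gap ratio 0.841), that of the H3K27 methylation genes was high on control array 1 (0.903), and that of the T cell markers was low on an emodin array (0.840). Of the array measures, the 75th percentile was high on IL4 array 1 (0.903; 813 against 761 to 766), the spike-in mean was high on control array 3 (0.903; 1.48 against 1.19 to 1.22), the spike-in slope was low on emodin array 3 (0.876; 0.938 against 1.05 to 1.07), and the local background was low on IL4 array 4 (1.00; 40 against 41). The spike-in signal over the 75th percentile lay 0.96 higher on emodin arrays than on control arrays (exact permutation test, two-sided, p = 0.0286), so the same added RNA was brighter relative to the sample RNA.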

How the results depend on the processing

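The count for IL4 against control was 3659 under the main choices, 5540 with normexp and the 75th percentile, 7321 with no filter on dim probes and 824 at least 2-fold. For IL4 plus emodin against IL4, 13750 became 22743 with no filter and 3828 at least 2-fold. Against control, 13125 became 19856 and 3474. The 2090 genes moved back became 3382 with normexp and the 75th percentile, 5616 with no filter and 434 at least 2-fold. The counts with no filter cover 37018 genes, including undetected ones, and cannot be read as responding genes. There the median difference of all genes was -0.13 for IL4 against control and 0.49 for emodin against IL4. Negative-control signal averaged 55.75 on control, 51.75 on IL4 and 60.88 on emodin arrays. With each array left out in turn the counts ranged over 2891 to 3775, 12974 to 13934, 12270 to 13031 and 1679 to 2124. The 0 genes with a response differing by labelled sex became 10 and 7 with no filter, and 0 to 5 and 0 to 119 with an array left out. Of the lists, 10, 8 and 6 were called; with an estimated correlation 1, 0 and 0, and with fry, which called many lists that camera did not, 22 for IL4 plus emodin against IL4 and 20 against control. With an array left out, they ranged over 8 to 11, 6 to 8, and 6. With quantile scaling, and with normexp then quantile, 4 lists were called for IL4 plus emodin against IL4, and with spike-in scaling 10 against control. Spike-in scaling gave 722 higher and 16834 lower genes for IL4 plus emodin against IL4, and quantile scaling 6134 and 6451. Spike-in scaling gave 860 and 15769 against control, and 1822 and 646 for IL4 against control, where no filter gave 1928 and 5393. The replicate number as a block changed the calls of *Retnla*, *Cyp1b1*, *Hmox1* and the MHC class II list for IL4 against control, and no other named call there, and it gave 5302 genes (2645 higher, 2657 lower) and 3050 moved back. In the other comparisons the numbers pair the arrays less clearly (same-number correlations 0.0934 to 0.438 and 0.0559 to 0.515), and as a hint only the block gave adjusted p values of 0.00522 for *Chil3*, 0.0165 for *Cyp1b1*, 0.0361 for *Nos2* and 0.0700 for the IL4 receptor and JAK-STAT list against IL4. The block also gave 0.0218 for *Chil3*, 0.0362 for *Kdm6b* and 0.0312 for *Retnla* against control. Leaving out number 1 of every group, a choice made after the data were seen, gave 3011, 12973, 12154 and 1750. For IL4 plus emodin against IL4, spike-in scaling reversed the medians of the classical inflammatory (-0.59), p53 target (-0.0399), matrix remodelling (-0.54), lysosome (-0.54) and ribosomal protein (-0.33) lists. The lysosome median was also -0.00709 with quantile scaling and -0.0253 with normexp then quantile. Spike-in scaling reversed *Ctsa* (-0.30), *Ezh2* (-0.0617), *Gpnmb* (-0.33), *Hmox1* (-0.76), *Nfkbia* (-0.0286), *Nos2* (-0.59), *Nqo1* (-1.02), *Rnf2* (-0.0105), *Rplp0* (-0.32), *Rplp2* (-0.29) and *Rps9* (-0.20), and *Il1b* was 0.0584 with normexp and the 75th percentile. Against control, spike-in scaling reversed the medians of the alternative activation (-0.12), classical inflammatory (-0.55), integrated stress response (-0.34), matrix remodelling (-0.42), lysosome (-0.35), ribosomal protein (-0.24), mast cell (-0.69) and mesothelial and fibroblast (-0.51) lists, and fry reversed the direction of the IL4 receptor and JAK-STAT list (median 0.25, adjusted p = 0.0189). Spike-in scaling also reversed *Ccl17* (-0.27), *Cyp1b1* (-0.95), *Ezh2* (-0.0943), *Gpnmb* (-0.20), *Kdm6b* (-0.67), *Lamp1* (-0.0827), *Nos2* (-0.37), *Rplp0* (-0.17, and -0.00653 with normexp then quantile), *Rps10* (-0.11), *Socs1* (-0.57) and *Tnf* (-0.64). The cause was not tested.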

Other observations

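Replication-dependent histone genes were grouped after some of them were seen among the largest rises with emodin, so no test of the group is given. Of 42 replication-dependent histone genes, 38 were higher and 2 lower on emodin than on IL4 arrays, with a median log2 difference of 1.97 (1.68 with quantile scaling, and 0.88 with spike-in scaling, where 25 were higher and 7 lower). *H4c17* rose by 4.44 ± 0.25 (SE, n = 4 per group), *H2bc8* by 2.82 ± 0.19, *H1f2* by 2.71 ± 0.12, *H1f6* by 2.67 ± 0.16 and *H4c11* by 2.52 ± 0.15, while *H2bc21* fell by 1.52 ± 0.10. Of 10 other histone genes, 5 were higher and 2 lower, with a median of 0.25 (0.04 with quantile scaling and -0.83 with spike-in scaling, where 1 was higher and 9 lower). IL4 alone raised none of the 42 and lowered 9. Of these 9, *H2bc23* lay below background on all control and IL4 arrays, and *H2ac6* was above it on only 2 control arrays and 1 IL4 array. *H2bc23*, *H1f3*, *H3c1*, *H3c8*, *H3c11* and *H2ac6* passed the filter only through the emodin arrays. That choice adds to the count of rises with emodin and to their median. The cell cycle list did not rise along with them (8 higher, 13 lower of 32; adjusted p = 0.307).

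Some alternative activation genes that IL4 did not raise also changed with emodin. *Il1rn*, which IL4 lowered by 0.96, rose by 2.17 with emodin, and *Tgm2* rose by 1.41 (0.32 and not called with spike-in scaling, adjusted p = 0.143). *Dcstamp* fell by 2.68 while its partner in cell fusion, *Ocstamp*, was lowered and no longer called against control. With spike-in scaling *Ocstamp* lay below control (-1.01, adjusted p = 0.000162).

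The emodin arrays differed from the IL4 arrays at 65.9% of genes, and all lay on another slide and in another slide row. The probe test below was fixed before the result was seen, and the spike-in test was chosen after it. Of 10 spike-ins, the 7 well above background on all arrays differed in their shifts by 0.214 at most, over a span of 10.3 log2 units. The median size among called genes was 0.71, so over that span a distortion by brightness cannot be the whole cause. The dimmer spike-ins, which were left out, shifted by 0.278, 0.796 and 0.874, so the dim end is not covered. Differences of single probes between slides cannot be the whole cause either. A second probe of the same gene gave log2 differences with a correlation of 0.595 over 3367 genes. Such differences may still contribute, as the second probe had the same sign for 79.7% of 2334 called genes. For IL4 against control, within a slide, the correlation was 0.751 and the same sign was found for 94.2%. A batch of RNA, labelling or culture shared by the emodin arrays could account for part of the differences, and the data cannot tell, since 0 emodin arrays lay on the slide of the others.

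No Y-linked gene was detected on the 6 arrays labelled male, and these tests were chosen after that was seen. Failed Y-linked probes alone do not account for it, as *Xist* lay well above background on 6 of the 6. An exchange of the sexes does not either, as 0 arrays labelled female had Y-linked signal. Female RNA under male labels would leave *Xist* alike, and its mean differed by -0.139 between arrays labelled male and female (exact permutation test, two-sided, p = 0.652). That test ignored the groups, while *Xist* lay at 0.89 to 1.43 on emodin arrays and -0.01 to 0.53 on the others. Its p therefore does not measure how alike the labelled sexes are.

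Fibroblast and mast cell markers followed the replicate number in every group, a test of slide position being fixed before the result was seen and one of shared cells chosen after. The fibroblast list ranged over 1.96 between numbers, while 1000 random lists of the same brightness ranged over 0.432 at most, so a general effect of the slide column does not explain it. Shared cells per number fit, as the number explained 99.4% of the variance of that list within groups (exact permutation test over 576 arrangements, p = 0.00174). It also explained 77.5% for the alternative activation list (exact permutation test, p = 0.00694), 88.0% for *Retnla* and 80.4% for *Chil3*, against 38.8% for the macrophage markers (exact permutation test, p = 0.382).

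For the counts of changed genes, each of the 3 comparisons was set against all 35 splits of its 8 arrays, chosen before the result was seen. The true split, 1 of 35, gave the largest count each time, and no other split gave more than 1 gene. Where groups differ at many genes, a mixed split puts that difference into its spread and calls few. The true split is also the split by slide for both emodin comparisons, and by slide row for IL4 against control and emodin against IL4. These counts therefore cannot tell treatment from position. Signal over background limits what can be said of *Ccl17*, *Il6* and *Il1b*, each of which lay below background on most or all arrays of at least 1 group.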
